A study of Homo sapiens with 18 samples.

How the data were processed

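The files hold bulk RNA sequencing of human intestinal organoids grown from H1, an established embryonic stem cell line. There are 18 libraries in 6 groups of 3, and the labels call the cell type mixed and the genotype WT. The labels name the groups spheroid, d6 si groove, d14 si groove, d14 HIO, d14 c-groove and d14 HCO, and do not spell out si, c, HIO or HCO. Spheroid, d14 HIO and d14 HCO carry the treatment conventional, and the 3 groove groups carry a scaffolding tray. The series title concerns mesenchymal WNT2B and the small intestinal epithelium. The design text of the series names single nucleus sequencing of transplanted organoids, which was not among the files analysed here.

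Per the labels, RNA was extracted with a column kit and made into libraries with a stranded mRNA protocol. The aligner, the counting tool, the genome build and the annotation are not given in the sources used here, so genes are named by symbol and no coordinates are given. The deposited count table holds whole numbers per gene for each library, read here as rounded estimated counts (expected counts), neither scaled nor pooled. Among 4950 genes with at least 500 counts, the ratio of TPM to count deviated between libraries by a median of 0.0532 on the log2 scale, and 16.8% of the values were more than 10% off, as happens where gene lengths are estimated library by library. The deposited TPM table was scaled by the authors for gene length, and each library's TPM values sum to between 999998 and 1000002.

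Of 36592 genes in the count table, 6364 had no count in any library. The low-count filter of edgeR (filterByExpr on the 6 groups) left 18701 genes for testing and removed 17891. Counts were scaled with TMM factors, and levels are given as CPM, counts scaled to a common library total with these factors. All 18 libraries were fitted together with 1 mean per group and no other term, with the robust quasi-likelihood test of edgeR 4.0.16 in R 4.3.3. P-values were adjusted over all tested genes by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. The common dispersion was 0.0221. Log2 changes are given with their SE and levels as the mean ± SD of 3 libraries. For a gene with no count in a group, the ratio is a lower bound against 3 counts, averaged over the libraries of that group. For 1 to 3 counts in the group, the ratio has a 95% counting interval. Such floors and intervals cover counting error only.

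The comparisons were 7 pairs of groups and 1 interaction, the tray effect of the si arm minus that of the c arm. In these, d14 HIO stands as the conventional counterpart of d14 si groove, and d14 HCO as that of d14 c-groove. These pairings, the tests, the rule for naming genes, the gene lists and the alternatives were chosen before the data were examined, except where the text says otherwise. Each comparison names the 6 largest rises and the 6 largest falls among called genes with 5 CPM or more in the higher group, a named symbol and no overlap between the groups. To these the rule adds up to 3 members in each direction of the 6 called lists with the smallest p, and 8 fixed genes, among them WNT2B, LGR5, CDX2, GATA4, PDX1, HOXA13 and HOXD13. Any list member may also be named as a measured member of its list. Only part of the named set is printed, and 1 fixed gene and 3 others that the rule chose are not reported here or counted among the named results.

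Hand-written lists, 41 in all with 715 entries, cover cell types, regions of the gut, signalling pathways, metabolism and stress. The count table matched 713 entries, 15 of them through an older symbol. Lists were tested with camera of limma 3.58.1, with a preset correlation between genes of 0.01 and, as an alternative, an estimated correlation, adjusted over the lists of each comparison. The number of called members is given over all genes tested and adjusted over the list alone.

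The alternatives were DESeq2 1.42.0, relative log expression size factors, no low-count filter, a filter of 1 CPM in 3 libraries, and a fit of only the groups compared. Further ones were limma on log2(TPM + 1) and on log2(TPM + 0.1), the replicate number as a block, sequencing run as a term where d6 si groove links the runs, and leaving out each library. The limma fits used the deposited TPM without TMM factors, for 17706 genes with 1 TPM or more in 3 libraries. No column was left out. Recovery was tested on simulated data before the real comparisons were run. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.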

Results

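RNA levels were measured in H1-derived intestinal organoid cultures at 3 stages: spheroid, day 6 in the si groove tray, and day 14 in 4 cultures, with 3 libraries in each of the 6 groups. Total counts ran from 16451025 to 32526711 per library, so that 3 counts in a library correspond to 0.0960 to 0.173 counts per 1e6 (CPM). Library totals ran from 21756963 to 32526711 in spheroid, 18550004 to 26035300 in d6 si groove, 26085602 to 29941156 in d14 si groove, 16451025 to 20864707 in d14 HIO, 20819843 to 22065552 in d14 c-groove and 17629913 to 18522119 in d14 HCO. The first principal component held 44.7% of the variance and parted d14 c-groove and d14 HCO from the other 12 libraries. Mitochondrially encoded genes took 0.656 ± 0.0702% of counts in d14 HIO and 2.33 ± 0.293% in d14 si groove, with 2.37 ± 0.183% in d14 HCO, 1.59 ± 0.161% in d14 c-groove, 1.57 ± 0.133% in d6 si groove and 1.63 ± 0.369% in spheroid. The labels place spheroid and d6 si groove replicates 1 and 2 in run2676, d6 si groove replicate 3 and d14 si groove in run0208, and the other day 14 groups in run0337. They do not say whether replicates come from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

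**Figure D1:**
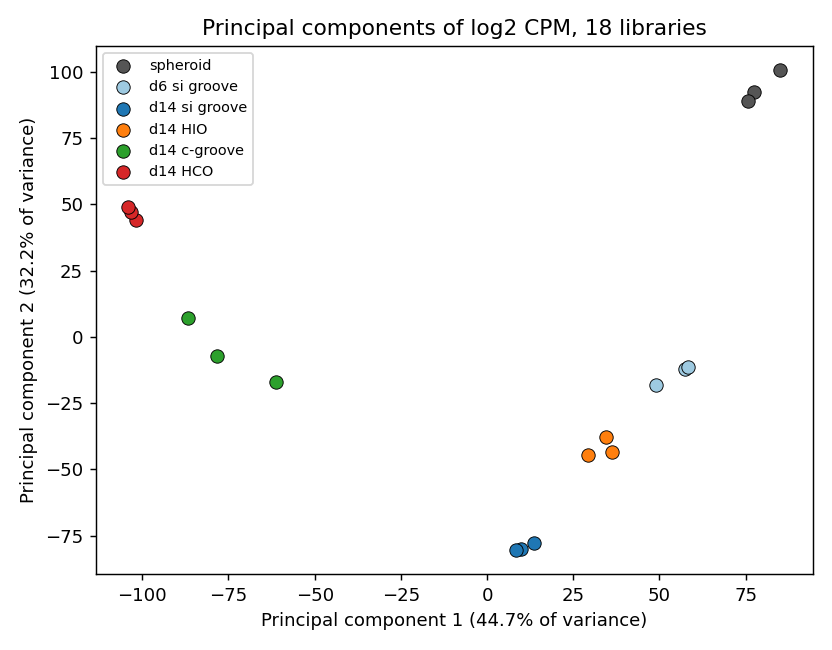
Principal components 1 (x axis, 44.7% of variance) and 2 (y axis, 32.2%) of log2 CPM, 1 point per library, coloured by group. On component 1 the d14 c-groove and d14 HCO libraries sit between -104 and -61.2, and the other 12 libraries between 8.36 and 85.0.

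At day 14 the si arm was compared between the tray and conventional culture, d14 si groove against d14 HIO. Genes induced by low oxygen stood higher in the tray. NDRG1, a hypoxia-induced stress gene, averaged 1309 ± 40.8 CPM in the tray and 138.6 ± 23.2 CPM in d14 HIO, a log2 change of 3.24 ± 0.13. VEGFA, which encodes a growth factor for blood vessels, averaged 714 ± 38.2 and 74.8 ± 31.8 CPM, and CA9, a carbonic anhydrase, rose by 4.23 ± 0.40 on the log2 scale. Epithelial genes were also higher in the tray: CDH1, which encodes E-cadherin, averaged 391 ± 15.0 against 88.0 ± 15.7 CPM, and the keratin gene KRT19 averaged 841 ± 46.3 against 189.5 ± 26.3 CPM. PCNA, the sliding clamp of DNA replication, fell from 201.5 ± 20.03 CPM in d14 HIO to 67.7 ± 5.38 CPM.

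Of the 20 hypoxia genes tested, 20 rose in the tray, LOX among them with a log2 change of 2.75 ± 0.16 (camera adjusted p = 4.8e-20). The call was lost at adjusted p = 0.0628 with an estimated correlation. From spheroid to d14 HIO the hypoxia list had a median log2 change of -1.09. In the si tray the median was -0.26 from spheroid to day 6 and 1.01 from day 6 to day 14. The difference at day 14 therefore need not be a rise in the tray alone. Glycolysis genes moved less evenly: 12 of 17 rose, with the lactate transporter SLC16A3 up by 2.81 ± 0.12, and 2 fell, GAPDH among them by 0.43 ± 0.08 on the log2 scale (5 lower from log2(TPM + 1); adjusted p = 2.41e-09, and adjusted p = 0.0662 with an estimated correlation). All 26 proliferation genes fell, MCM4 by 1.40 ± 0.15 (adjusted p = 4.61e-11, and adjusted p = 0.3 with an estimated correlation). Of the 20 intestinal epithelium genes, 17 rose and none fell (adjusted p = 1.7e-11, and adjusted p = 0.0628 with an estimated correlation). All 15 lipid absorption genes rose, among them APOB and MTTP, which build lipoproteins in enterocytes, by 2.22 ± 0.34 and 2.11 ± 0.35 (adjusted p = 2.48e-05, and adjusted p = 0.158 with an estimated correlation). Of 20 extracellular matrix genes, 16 rose, with COL12A1 at 125 ± 8.23 against 14.8 ± 1.52 CPM and LAMC1 up by 1.35 ± 0.07 (adjusted p = 2.41e-09, and adjusted p = 0.107 with an estimated correlation). Endothelial genes rose in 12 of 14 cases, PECAM1 by 3.81 ± 0.36 and CDH5 by 3.34 ± 0.41 (adjusted p = 2.96e-07, and adjusted p = 0.198 with an estimated correlation). All 13 mitochondrially encoded genes were higher in the tray, MT-CO1 at 8030 ± 804 against 1636 ± 185 CPM (adjusted p = 1.7e-16, and adjusted p = 0.107 with an estimated correlation). Adjusted over the list alone, 1 extracellular matrix gene also fell, and the other counts of this paragraph were the same.

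Genes of the posterior gut and of neural cells were lower in the tray. The homeobox genes HOXA13 and HOXD13, expressed in the hindgut, averaged 1.16 ± 0.228 and 0.530 ± 0.210 CPM in d14 si groove, and 31.8 ± 4.60 and 29.1 ± 5.17 CPM in d14 HIO. Of the 17 colon and posterior genes, 16 fell (adjusted p = 1.37e-07, and adjusted p = 0.107 with an estimated correlation). The neural crest gene SOX10 averaged 0.0922 ± 0.0167 CPM in the tray and 51.3 ± 36.8 CPM in d14 HIO, whose 3 libraries held 77.5, 67.2 and 9.24 CPM. Of 15 neural and glial genes, 14 fell (15 adjusted over the list alone; adjusted p = 4.91e-07, and adjusted p = 0.211 with an estimated correlation). Of 21 genes for WNT ligands and R-spondins, 11 fell and none rose, over all genes as adjusted over the list alone (adjusted p = 0.00809, and adjusted p = 0.324 with an estimated correlation). Among other fixed genes, CDX2, GATA4 and PDX1 rose by 1.14 ± 0.28, 2.10 ± 0.34 and 2.46 ± 0.43, and LGR5 fell by 2.53 ± 0.49 (-1.65 without d14 HIO replicate 1). WNT2B itself averaged 5.30 ± 0.416 and 4.58 ± 1.44 CPM, and its log2 difference of 0.21 ± 0.50 did not pass the test (adjusted p = 0.74).

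The largest rises in the tray included ASPN, a matrix proteoglycan gene, by 8.14 ± 0.38, and CA7 by 8.01 ± 0.39 on the log2 scale. DMBT1, a mucosal defence gene, rose from 1.46 ± 0.164 to 195 ± 19.4 CPM. LYVE1 and MRC1, known in lymphatic vessels and macrophages, rose by 8.02 ± 0.75 and 7.13 ± 1.12, and by 7.30 and 5.81 without d14 si groove replicate 1. In total 5608 genes were higher and 5156 lower in the tray, 3139 and 1723 of them by at least 2-fold, and 65.2% of genes showed no overlap between the groups, where chance gives 10%. Camera called 25 lists with the preset correlation and 0 with an estimated correlation, where 10 lists had an unadjusted p under 0.05. Among called genes the share higher in the tray was 52.1% from counts and 35.9% from log2(TPM + 1). The median log2 change of all genes was 0.024 from counts and -0.178 from log2(TPM + 1), and log2(TPM + 0.1) called 3487 genes higher. No run holds both groups, so run and culture cannot be told apart here by a fit.

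The same question was asked in the c arm, d14 c-groove against d14 HCO, where all 6 libraries were in run0337. Genes induced by low oxygen were again higher in the tray: BNIP3, a mitophagy gene, averaged 105 ± 16.8 against 9.46 ± 0.367 CPM, and NDRG1 averaged 769 ± 132 against 103 ± 11.9 CPM. The glucose transporter gene SLC2A1 rose from 188 ± 11.4 to 1716 ± 157 CPM, and the glycolytic enzyme gene ENO2 from 4.92 ± 0.122 to 159 ± 33.9 CPM. Mesenchymal genes were higher as well: VIM, which encodes vimentin, averaged 2095 ± 158 against 384 ± 48.8 CPM, and POSTN, a matrix gene, 218 ± 90.8 against 8.34 ± 2.44 CPM. S100A9, which encodes a calcium-binding protein of myeloid and squamous cells, fell from 204 ± 27.5 to 1.48 ± 1.098 CPM.

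All 20 hypoxia genes rose, CA9 by 7.23 ± 0.56 (camera adjusted p = 3.78e-32, and adjusted p = 0.0113 with an estimated correlation). Of 17 glycolysis genes 15 rose, PGK1 by 1.89 ± 0.07 (adjusted p = 8.44e-28, and adjusted p = 0.00179 with an estimated correlation). Of 20 extracellular matrix genes 19 rose, COL5A2 by 2.41 ± 0.14 and BGN by 3.56 ± 0.22, and COL12A1 fell by 1.60 ± 0.16 (adjusted p = 4.85e-17, and adjusted p = 0.0202 with an estimated correlation). Among 20 general mesenchyme genes 18 rose, PDGFRA by 2.96 ± 0.24, and 1 fell (adjusted p = 5.11e-13, and adjusted p = 0.0793 with an estimated correlation). Proliferation genes fell in 25 of 26 cases, AURKA by 1.46 ± 0.11 and MCM4 by 1.58 ± 0.16 (adjusted p = 1.6e-12, and adjusted p = 0.3 with an estimated correlation). Endothelial genes rose in 12 of 14 cases, PECAM1 by 4.41 ± 0.53, CDH5 by 4.57 ± 0.57 and the VEGF receptor gene KDR by 2.51 ± 0.26 (adjusted p = 7.29e-08, and adjusted p = 0.218 with an estimated correlation). Mitochondrially encoded genes moved the other way than in the si arm, with 11 of 13 lower in the tray (adjusted p = 0.00171, and adjusted p = 0.57 with an estimated correlation). Of 14 replication-dependent histone genes 13 fell (adjusted p = 1.18e-06, and adjusted p = 0.0167 with an estimated correlation), and reads of these near-identical copies are assigned with less certainty. Some members lay near the floor: HIST1H1B averaged 1.60 CPM in d14 HCO with 2 counts in d14 c-groove, and HIST1H1D 0.628 CPM with 1 count. The libraries followed an mRNA protocol, and how evenly it captured histone transcripts was not tested. Adjusted over the list alone, 12 mitochondrially encoded genes fell, and the other counts of this paragraph were the same.

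CDX2 and several genes of the proximal small intestine were higher in the c tray, while the intestinal epithelium list was divided. CDX2, a master gene of intestinal fate, averaged 25.2 ± 14.3 against 2.24 ± 0.463 CPM, and PDX1 rose by 4.68 ± 0.81 (5.28 without d14 HCO replicate 1). GATA4, a gene of the proximal intestine, rose by 1.95 ± 0.37. Of 20 intestinal epithelium genes 7 rose, 4 fell and 9 did not pass, the same adjusted over the list alone, and camera did not call the list (adjusted p = 0.537). Of 15 proximal small intestine genes 9 rose and 1 fell, the same adjusted over the list alone (adjusted p = 0.00171, and adjusted p = 0.223 with an estimated correlation). LCN15, NPPB and NKX2-3, with no count in d14 HCO, were at least 246-fold, 104-fold and 40.4-fold higher at 40.9 ± 31.8, 17.4 ± 4.75 and 6.72 ± 5.50 CPM. The d14 c-groove libraries differed among themselves: on principal component 1 replicate 1 lay at -61.2, nearer the si arm than replicates 2 and 3 at -86.7 and -78.3. Without d14 c-groove replicate 2, camera also called the enterocyte, goblet and lipid absorption lists, at adjusted p of 0.0434, 0.0143 and 0.00106. KRT20, a gene of mature surface epithelium, fell by 6.85 ± 0.62, and S100A9 fell by 7.10 ± 0.37; without d14 c-groove replicate 2 the changes were -7.48 and -7.91. Of 21 WNT ligand and R-spondin genes 13 rose and 1 fell, or 2 adjusted over the list alone (adjusted p = 0.0432, and adjusted p = 0.517 with an estimated correlation). That call was lost without d14 c-groove replicate 1, d14 c-groove replicate 2 or d14 HCO replicate 3, at adjusted p of 0.1, 0.0639 and 0.0985. WNT2B averaged 2.80 ± 0.819 CPM in the tray, above all 3 d14 HCO libraries at 0.718 ± 0.226, a log2 change of 1.95 ± 0.62 (adjusted p = 0.0144). The WNT2B call was lost without d14 c-groove replicate 1 (1.69), d14 HCO replicate 1 (1.85) or d14 HCO replicate 2 (1.84), and from log2(TPM + 1) (0.23) and log2(TPM + 0.1) (0.56). LGR5, HOXA13 and HOXD13 did not pass the test, with log2 differences of 0.12, -0.31 and 0.46 and adjusted p of 0.838, 0.642 and 0.458.

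In the c arm 4771 genes were higher and 4370 lower in the tray, 2870 and 1281 of them by at least 2-fold. The groups did not overlap for 64.3% of genes, where chance gives 10%. Camera called 20 lists with the preset correlation and 4 with an estimated correlation.

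Across the 18701 genes the log2 changes of both arms had a Pearson correlation of 0.203, where genes are not independent replicates. Of 5944 genes called in both arms 4232, or 71.2%, went the same way: 2232 were higher in both trays, where independent lists of these sizes would share 1431, and 2000 were lower in both, against 1205. Another 826 genes were higher in the si tray and lower in the c tray, and 886 went the opposite way. The test of the difference itself called 7654 genes, 3772 with the larger change in the si arm and 3882 with the larger change in the c arm, in signed log2 terms. NDRG1 was not among them, with a log2 difference of 0.34 ± 0.17 (adjusted p = 0.121). CA9 was, with a difference of -3.01, since its rise was greater in the c arm. The difference for WNT2B, -1.74 ± 0.80, did not pass (adjusted p = 0.0912). Run enters this difference, since of these 4 groups d14 si groove alone was sequenced in run0208.

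**Figure D2:**
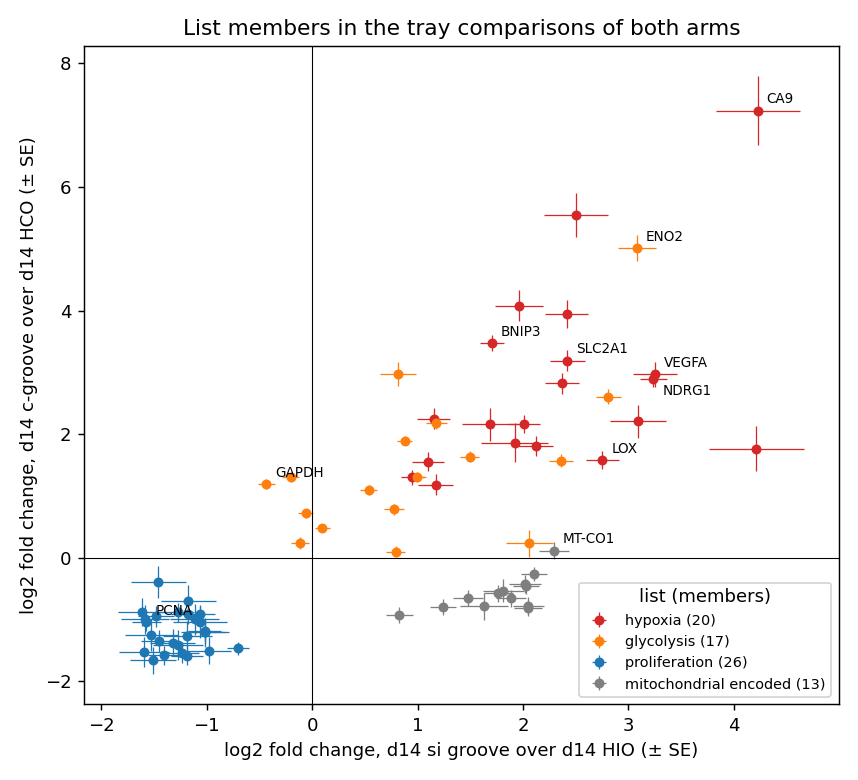
Log2 fold change of d14 si groove over d14 HIO (x axis) and of d14 c-groove over d14 HCO (y axis), 1 point per gene with bars of 1 SE, for 20 hypoxia, 17 glycolysis, 26 proliferation and 13 mitochondrially encoded genes. Hypoxia genes lie above 0 on both axes, with CA9 at 4.23 and 7.23, proliferation genes lie below 0 on both, and mitochondrially encoded genes lie right of 0 on the x axis and, apart from MT-CO1, below 0 on the y axis.

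**Figure D3:**
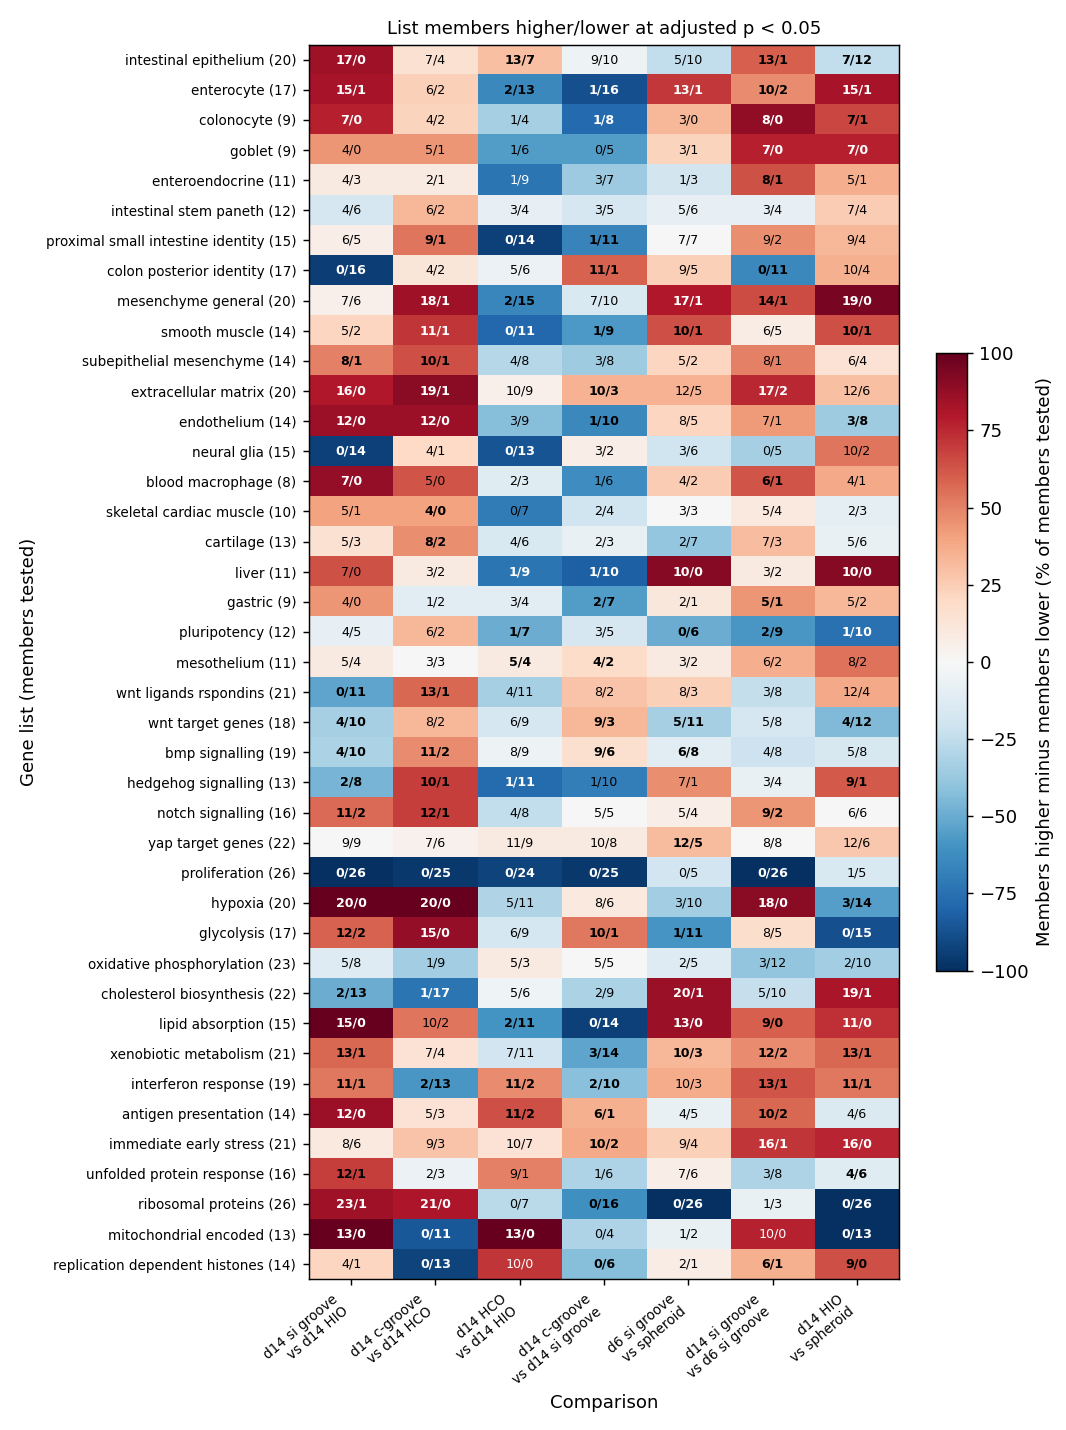
Each of 41 gene lists (y axis, members tested in brackets) in 7 comparisons (x axis), with the number of members called higher and lower by edgeR at an adjusted p under 0.05. Colour gives members higher minus members lower in percent of members tested, and bold marks lists called by camera with the preset correlation. The hypoxia list reads 20/0 in both tray comparisons at day 14.

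The conventional cultures at day 14 were compared within run0337, d14 HCO against d14 HIO. Of the epithelial genes, KRT19 and CDH1 were higher in d14 HCO, and CDX2 and HNF4A were lower. KRT19 averaged 2400 ± 43.4 against 189.5 ± 26.3 CPM, and CDH1 averaged 859 ± 7.30 against 88.0 ± 15.7 CPM. CDX2 averaged 2.24 ± 0.463 against 43.9 ± 10.2 CPM, and HNF4A, a transcription factor gene of enterocytes, fell by 4.18 ± 0.29 on the log2 scale. SPRR3 and IVL, genes of stratified epithelium, averaged 336.6 ± 20.3 and 285 ± 9.61 CPM in d14 HCO. SPRR3 rose by 11.98 ± 0.29 (12.59 without d14 HIO replicate 1), and IVL, with 1 count in d14 HIO, had a ratio of 18310 with a 95% counting interval of 3286 to 723100.

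**Figure D4:**
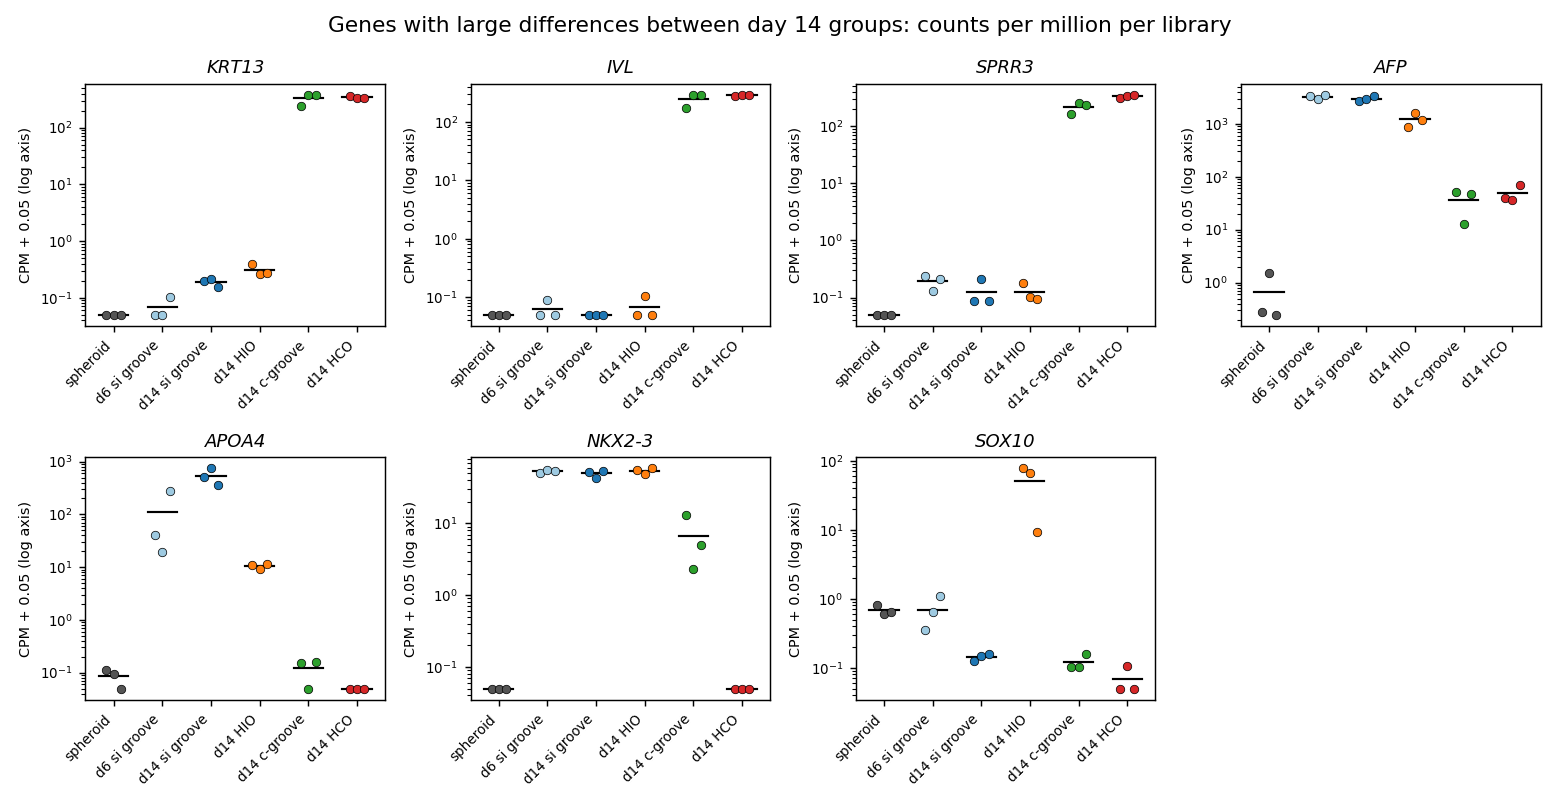
CPM plus 0.05 (y axis, log scale) of 7 genes in each library of the 6 groups (x axis); points are libraries and lines are means of 3. KRT13, IVL and SPRR3 sit above 100 CPM in the d14 c-groove and d14 HCO libraries and under 1 CPM in the other 12, and SOX10 sits highest in d14 HIO, at 9.24 to 77.5 CPM.

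The intestinal epithelium list was divided, with 13 of 20 genes higher in d14 HCO and 7 lower. The tight junction gene CLDN4 rose by 3.28 ± 0.15, and LGALS4, a galectin gene of enterocytes, fell by 6.49 ± 0.55 (camera adjusted p = 1.42e-05, and adjusted p = 0.226 with an estimated correlation). Of 15 proximal small intestine genes 14 fell, HOXC4 by 6.34 ± 0.28, GATA5 by 4.07 ± 0.33 and GATA6 by 2.35 ± 0.20 (adjusted p = 1.42e-05, and adjusted p = 0.226 with an estimated correlation). Enterocyte genes fell in 13 of 17 cases and rose in 2 (adjusted p = 0.00376, and adjusted p = 0.418 with an estimated correlation). Mesenchyme genes fell in 15 of 20 cases and rose in 2: POSTN averaged 8.34 ± 2.44 against 475 ± 26.3 CPM, and PDGFRA 25.4 ± 5.67 against 513 ± 22.3 CPM, while LUM rose by 1.08 ± 0.25 (adjusted p = 2.12e-05, and adjusted p = 0.344 with an estimated correlation). Of 13 hedgehog pathway genes 11 fell and 1 rose, with falls of GAS1 by 4.02 ± 0.16, GLI1 by 3.45 ± 0.27 and SMO by 1.77 ± 0.14 (adjusted p = 5.41e-06, and adjusted p = 0.226 with an estimated correlation). Antigen presentation genes rose in 11 of 14 cases and fell in 2, with rises of TAP1 by 5.51 ± 0.29 and HLA-E by 2.32 ± 0.13, while CD74 fell by 1.02 ± 0.14 (adjusted p = 1.42e-05, and adjusted p = 0.226 with an estimated correlation). All 13 mitochondrially encoded genes were higher in d14 HCO, MT-ATP6 by 2.49 ± 0.14 (adjusted p = 6.84e-13, and adjusted p = 0.226 with an estimated correlation). Of 15 neural and glial genes 13 were lower (adjusted p = 0.00179, and adjusted p = 0.475 with an estimated correlation). All counts of this paragraph were the same adjusted over the list alone.

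LCN15 and NKX2-3, a mesenchymal gene of the gut, had no count in d14 HCO and were at least 380-fold and 325-fold lower than in d14 HIO. MS4A7, a macrophage gene, had no count in d14 HIO and was at least 260-fold higher at 36.8 ± 4.83 CPM. The 8 genes of the blood and macrophage list leaned the other way, with a median log2 change of -1.17. WNT2B fell from 4.58 ± 1.44 to 0.718 ± 0.226 CPM, lower in all 3 d14 HCO libraries, a log2 change of -2.66 ± 0.60 (adjusted p = 0.000919). PDX1 fell by 5.87 ± 0.75 (-6.46 without d14 HCO replicate 1). HOXD13 rose by 1.55 ± 0.50 (adjusted p = 0.0116), a call lost without d14 HIO replicate 2 (1.42) and from log2(TPM + 0.1) (1.28). In total 5678 genes were higher in d14 HCO and 6332 lower, 3032 and 3823 of them by at least 2-fold, and the groups did not overlap for 73.9% of genes, where chance gives 10%. Among called genes the share higher in d14 HCO was 47.3% from counts and 35.4% from log2(TPM + 1). The median log2 change of all genes was -0.072 from counts and -0.237 from log2(TPM + 1). Camera called 15 lists with the preset correlation and 0 with an estimated correlation, where 8 had an unadjusted p under 0.05.

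Between the trays at day 14, d14 c-groove against d14 si groove, the stratified epithelium genes KRT13, IVL and SPRR3 were higher in the c arm and genes of lipid-absorbing enterocytes and liver lower. KRT13 averaged 334 ± 78.0 against 0.138 ± 0.0283 CPM, and IVL, with no count in d14 si groove, was at least 2391-fold higher at 249.8 ± 65.0 CPM. SPRR3 rose by 11.31 ± 0.28 (12.36 without d14 si groove replicate 2). AFP, the fetal albumin-like protein of liver and yolk sac, averaged 36.8 ± 21.1 against 2964 ± 311 CPM. APOB averaged 2.63 ± 1.81 against 299.5 ± 71.9 CPM, and APOC3, with no count in d14 c-groove, was at least 404-fold lower.

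Of 17 enterocyte genes 16 fell and 1, the peptidase gene MME, rose by 2.11 ± 0.28 (camera adjusted p = 1.91e-07, and adjusted p = 0.207 with an estimated correlation). Of 15 lipid absorption genes 14 fell, MTTP by 4.28 ± 0.40 and APOA1 by 4.31 ± 0.38 (adjusted p = 3.12e-07, and adjusted p = 0.207 with an estimated correlation). Liver genes fell in 10 of 11 cases and rose in 1, with falls of FGB by 5.78 ± 0.45 and FGG by 6.01 ± 0.52, both fibrinogen genes (adjusted p = 2.91e-05, and adjusted p = 0.284 with an estimated correlation). Colon and posterior genes rose in 11 of 17 cases and fell in 1: MSX2 rose by 5.67 ± 0.31, and HOXA9 fell by 0.57 ± 0.16 (adjusted p = 7.72e-05, and adjusted p = 0.284 with an estimated correlation). HOXD13 averaged 117 ± 11.5 against 0.530 ± 0.210 CPM, and LGR5, a stem cell receptor gene, 8.12 ± 0.252 against 0.613 ± 0.0602 CPM. Of 15 proximal small intestine genes 11 fell and 1 rose, with falls of HOXC4 by 2.56 ± 0.19 and ONECUT2 by 4.05 ± 0.39 (-4.68 without d14 c-groove replicate 1), and PDX1 fell by 3.65 ± 0.46 (adjusted p = 0.000238, and adjusted p = 0.207 with an estimated correlation). Proliferation genes fell in 25 of 26 cases, PLK1 by 1.26 ± 0.22 (adjusted p = 3.02e-05, and adjusted p = 0.509 with an estimated correlation). Adjusted over the list alone, 1 lipid absorption gene also rose and 2 colon and posterior genes fell, and the other counts of this paragraph were the same. WNT2B averaged 2.80 ± 0.819 and 5.30 ± 0.416 CPM, lower in all 3 d14 c-groove libraries, a log2 difference of -0.92 ± 0.52 that did not pass (adjusted p = 0.142); it passed in the fit of both groups alone (-0.88) and from log2(TPM + 1) (-0.61).

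In this comparison 4892 genes were higher in d14 c-groove and 5542 lower, 2069 and 2818 of them by at least 2-fold, and the groups did not overlap for 63.2% of genes, where chance gives 10%. Camera called 21 lists with the preset correlation and 0 with an estimated correlation, where 5 had an unadjusted p under 0.05. Across genes, the log2 difference between the arms had a Pearson correlation of 0.608 between the tray and conventional culture, and of 7681 genes called in both 6704, or 87.3%, went the same way. Of these, 3310 were higher in the c arm in both cultures, where independent lists would share 1485, and 3394 were lower in both, against 1876. The trays were sequenced in different runs, run0337 and run0208, so no within-run value exists.

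From spheroid to day 6 in the si groove tray, genes of mesenchyme, liver and enterocytes rose, and WNT target genes mostly fell. COL3A1, a fibrillar collagen gene, rose from 20.1 ± 9.03 to 3556 ± 356 CPM. AFP rose from 0.622 ± 0.712 to 3276 ± 351 CPM, a log2 change of 12.39 ± 0.67 (13.87 without spheroid replicate 2). SI, the sucrase-isomaltase gene of enterocytes, had no count in spheroid and was at least 230-fold higher at 28.5 ± 4.73 CPM. SP5, a direct WNT target, fell from 111 ± 17.6 to 2.61 ± 0.643 CPM, and AXIN2 fell from 238 ± 50.2 to 25.5 ± 3.85 CPM. FGF17, a growth factor gene of early embryos, fell by 10.15 ± 0.32 from 217 ± 12.8 CPM, with changes of -9.51 without d6 si groove replicate 2 and -11.04 without d6 si groove replicate 3.

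Among 20 mesenchyme genes 17 rose, POSTN by 6.66 ± 0.31, and PRRX1 fell by 1.92 ± 0.54, with changes of -3.37 without d6 si groove replicate 3 and, no longer called, -1.89 in the fit of both groups alone (camera adjusted p = 1.39e-15, and adjusted p = 0.0971 with an estimated correlation). Of 11 liver genes 10 rose: FGB averaged 1306 ± 108 against 0.163 ± 0.229 CPM, and SERPINA1 rose by 11.84 ± 0.66 (14.85 and 12.75 for both genes without spheroid replicate 2; adjusted p = 1.17e-09, and adjusted p = 0.168 with an estimated correlation). Smooth muscle genes rose in 10 of 14 cases and fell in 1, with rises of CALD1 by 1.51 ± 0.07 and LMOD1 by 4.83 ± 0.30 (adjusted p = 4.5e-08, and adjusted p = 0.0971 with an estimated correlation). Enterocyte genes rose in 13 of 17 cases and fell in 1, and DPP4 rose by 3.60 ± 0.23 (adjusted p = 8.39e-07, and adjusted p = 0.168 with an estimated correlation). Cholesterol biosynthesis genes rose in 20 of 22 cases and fell in 1 (adjusted p = 2.63e-06, and adjusted p = 0.168 with an estimated correlation). All 26 ribosomal protein genes fell, RPL11 by 0.88 ± 0.10 (adjusted p = 1.43e-08, and adjusted p = 0.47 with an estimated correlation). Among 18 WNT target genes 11 fell, NKD1 by 4.32 ± 0.24, and 5 rose, MYC by 1.39 ± 0.20 (adjusted p = 2.63e-06, and adjusted p = 0.168 with an estimated correlation). Adjusted over the list alone, 11 liver genes rose and 12 WNT target genes fell, and the other counts of this paragraph were the same.

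NKX2-3 had no count in spheroid and was at least 431-fold higher at day 6, and the early embryonic genes WNT8A and FGF4 had none at day 6 and were at least 77.9-fold and 39.1-fold lower. CDX2 fell from 619.7 ± 10.5 to 141 ± 3.33 CPM, and GATA4 rose by 3.73 ± 0.37. LGR5 fell by 5.53 ± 0.57 (-6.83 without d6 si groove replicate 3). HOXA13 and HOXD13 rested on d6 si groove replicate 3, the only day 6 library in run0208. HOXA13 stood at 23.9 CPM there and at 2.84 and 2.30 CPM in replicates 1 and 2, and its log2 change of 2.36 ± 0.64 (adjusted p = 0.00573) was 0.51 and not called without that library. HOXD13 had a log2 change of 3.12 ± 0.77 with that library and 1.24 without it. In total 4994 genes rose and 4408 fell, 2539 and 1789 of them by at least 2-fold, and the groups did not overlap for 54.4% of genes, where chance gives 10%. Within run2676, without d6 si groove replicate 3, 5026 genes rose and 4190 fell. Camera called 13 lists with the preset correlation and 0 with an estimated correlation, where 10 had an unadjusted p under 0.05. Among called genes the share higher at day 6 was 53.1% from counts and 70.4% from log2(TPM + 1), which called 2479 genes lower. The median log2 change of all genes was 0.013 from counts and 0.159 from log2(TPM + 1).

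From day 6 to day 14 in the si groove tray, genes of differentiated surface and secretory epithelium rose and proliferation genes fell. AGR2, a gene of mucus-producing cells, rose from 5.48 ± 1.71 to 417 ± 41.7 CPM, and the mucin gene MUC2 from 0.402 ± 0.158 to 11.3 ± 4.79 CPM. KRT20 and CEACAM7, genes of mature surface epithelium, had no count at day 6 and were at least 160-fold and 200-fold higher at day 14. DMBT1, with 1 count at day 6, had a ratio of 13820 with a 95% counting interval of 2481 to 545900. NDRG1 rose by 2.43 ± 0.13 and VEGFA by 2.71 ± 0.20. PCNA fell by 1.42 ± 0.14 and AURKA, a mitotic kinase gene, by 0.96 ± 0.10.

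All 26 proliferation genes fell (camera adjusted p = 8.08e-09, and adjusted p = 0.376 with an estimated correlation). Hypoxia genes rose in 18 of 20 cases, EGLN3 by 3.49 ± 0.21 (adjusted p = 1.1e-06, and adjusted p = 0.257 with an estimated correlation). Of 9 colonocyte genes 8 rose, the peptide hormone gene GUCA2B by at least 69.7-fold (adjusted p = 2.47e-05, and adjusted p = 0.257 with an estimated correlation). Goblet cell genes rose in 7 of 9 cases, TFF3 by 4.42 ± 0.42 (adjusted p = 0.00107, and adjusted p = 0.257 with an estimated correlation). Extracellular matrix genes rose in 17 of 20 cases, COL12A1 by 3.60 ± 0.18 and LAMA2 by 5.05 ± 0.31 (5.77 without d6 si groove replicate 3 and 4.08 with run as a term), while VCAN and FN1 fell by 1.21 ± 0.13 and 1.06 ± 0.20 (adjusted p = 8.94e-06, and adjusted p = 0.257 with an estimated correlation). Of 8 blood and macrophage genes 6 rose, LYZ by 7.30 ± 0.27 (6.42 with run as a term) and CD68 by 4.35 ± 0.27, and TYROBP fell by 2.41 ± 0.43, with a change of -3.06 without d14 si groove replicate 1 (camera adjusted p = 0.000161, and adjusted p = 0.246 with an estimated correlation). LYZ also stands in the list of intestinal stem and Paneth cells, so its rise is not particular to blood cells. All counts of this paragraph were the same adjusted over the list alone.

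PDX1 rose by 2.70 ± 0.43. HOXA13 and HOXD13 fell by 3.01 ± 0.67 and 3.51 ± 0.78, with changes of -1.16 and -1.64 without d6 si groove replicate 3, and of -4.35 and -4.88 with run as a term. WNT2B had a log2 difference of 0.66 ± 0.51 (adjusted p = 0.277), which was 1.40 and called without d6 si groove replicate 3 and -0.23 with run as a term. LGR5 had a difference of 1.30 ± 0.68 (adjusted p = 0.111), called by DESeq2 (1.30) and without d6 si groove replicate 3 (2.59), and -0.03 with run as a term. In total 5609 genes rose and 5423 fell, 3548 and 1513 of them by at least 2-fold, and the groups did not overlap for 63.0% of genes, where chance gives 10%. The run0208 libraries include 1 day 6 library and those of run2676 no day 14 library. With run as a term, 3149 genes rose and 2929 fell, but the term rests on d6 si groove replicate 3 and cannot part run from that library. Camera called 20 lists with the preset correlation and 0 with an estimated correlation, where 6 had an unadjusted p under 0.05.

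From spheroid to day 14 in conventional culture, d14 HIO against spheroid, mesenchyme genes rose, and genes of pluripotency, glycolysis and the ribosome fell. COL3A1 rose from 20.1 ± 9.03 to 4430 ± 531 CPM, and POSTN from 2.74 ± 0.383 to 475 ± 26.3 CPM. LIN28A, an RNA-binding protein gene of stem cells, fell from 1820 ± 38.4 to 69.7 ± 20.8 CPM. LDHA, which encodes lactate dehydrogenase, fell from 2213 ± 28.8 to 387 ± 25.1 CPM, and SLC16A3 from 223 ± 7.22 to 27.3 ± 6.04 CPM. HMGCS1, an enzyme gene of cholesterol synthesis, rose from 137 ± 15.6 to 518 ± 59.5 CPM.

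Of 20 mesenchyme genes 19 rose (camera adjusted p = 7.22e-18, and adjusted p = 0.0706 with an estimated correlation). Of 17 glycolysis genes 15 fell, PGAM1 by 1.71 ± 0.08, where log2(TPM + 1) gave 12 lower and 3 higher (adjusted p = 3.33e-15, and adjusted p = 0.0346 with an estimated correlation). All 26 ribosomal protein genes fell, RPL4 by 1.24 ± 0.08 and RPL23 by 1.28 ± 0.08 (adjusted p = 9.65e-17, and adjusted p = 0.247 with an estimated correlation). All 13 mitochondrially encoded genes were lower in d14 HIO, MT-CO3 by 1.98 ± 0.14 (adjusted p = 4.1e-08, and adjusted p = 0.247 with an estimated correlation). Cholesterol biosynthesis genes rose in 19 of 22 cases and fell in 1, with rises of INSIG1 by 2.48 ± 0.12 and MVK by 1.83 ± 0.13 (adjusted p = 1.05e-07, and adjusted p = 0.148 with an estimated correlation). Of 12 pluripotency genes 10 fell, DNMT3B by 2.38 ± 0.12, and LEFTY1 rose by 2.13 ± 0.47 (adjusted p = 2.71e-06, and adjusted p = 0.148 with an estimated correlation). Adjusted over the list alone, 16 glycolysis genes fell, and the other counts of this paragraph were the same. FGF17 fell by 9.92 ± 0.32, and MSGN1, a gene of presomitic mesoderm, had no count in d14 HIO and was at least 103-fold lower. CDX2 fell by 3.82 ± 0.31, and HOXA13 and HOXD13 rose by 4.13 ± 0.64 and 5.39 ± 0.71. WNT2B averaged 4.58 ± 1.44 and 2.10 ± 1.54 CPM, higher in all 3 d14 HIO libraries, a log2 difference of 1.09 ± 0.52 that did not pass (adjusted p = 0.0813). It was called from log2(TPM + 1) (0.70) and log2(TPM + 0.1) (1.56) and without spheroid replicate 1 (1.55).

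Between these groups 5906 genes rose and 5218 fell, 3444 and 2231 of them by at least 2-fold, and the groups did not overlap for 64.4% of genes, where chance gives 10%. From log2(TPM + 1), 8952 genes rose and 2379 fell, and 79.0% of called genes were higher in d14 HIO against 53.1% from counts. The median log2 change of all genes was 0.39 against 0.06 from counts. TMM factors, which the TPM fits do not apply, were 1.12 to 1.14 in d14 HIO and 0.93 to 0.96 in spheroid. Counts and TPM therefore differ here in scaling as well. Camera called 22 lists with the preset correlation and 1, glycolysis, with an estimated correlation, where 8 had an unadjusted p under 0.05. No run holds both groups.

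**Figure D5:**
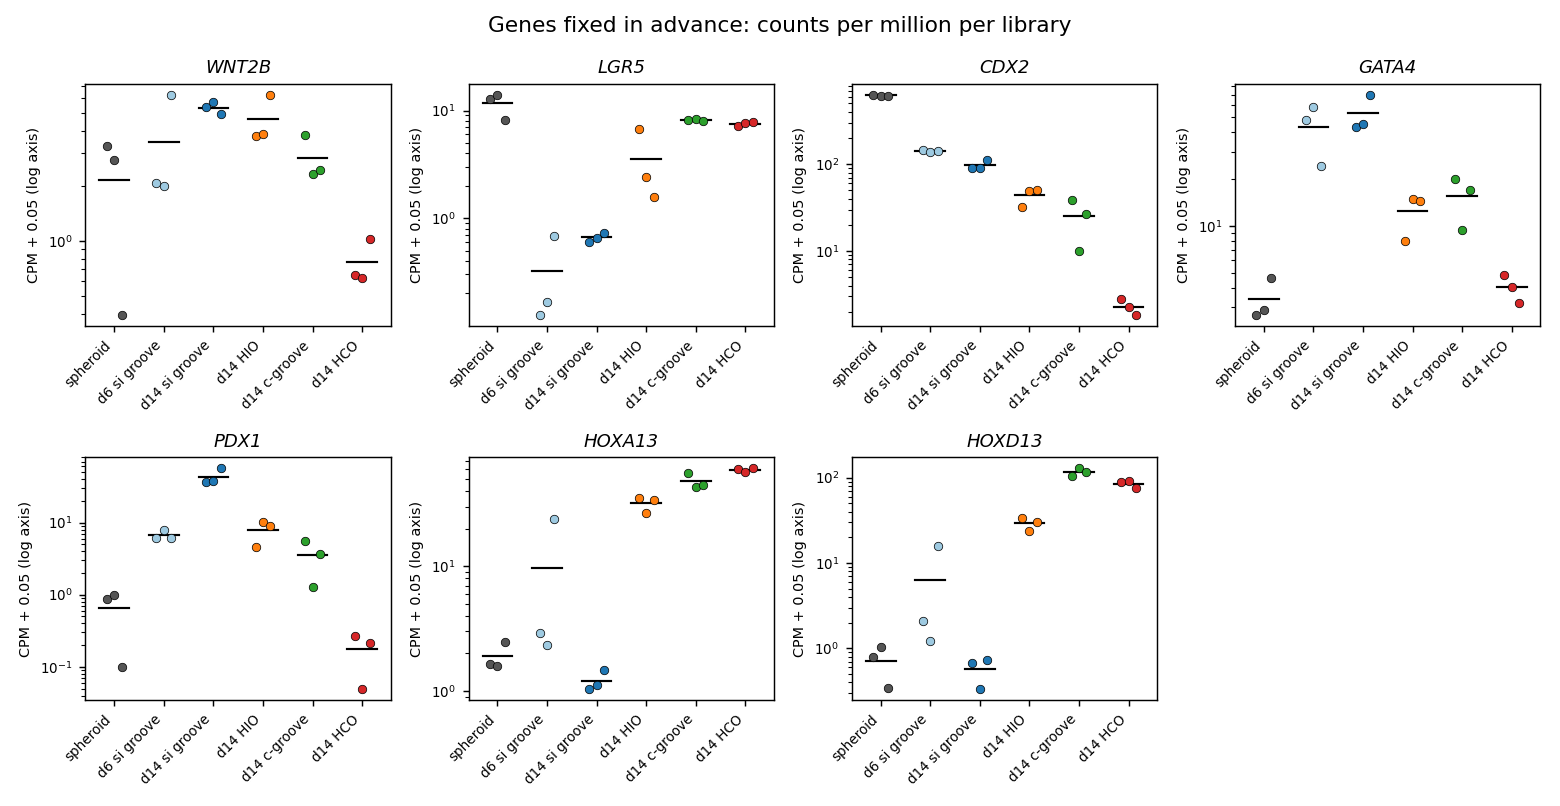
CPM plus 0.05 (y axis, log scale) of 7 genes fixed in advance, in each library of the 6 groups (x axis); points are libraries and lines are means of 3. Mean WNT2B ran from 0.718 CPM in d14 HCO to 5.30 CPM in d14 si groove, and d6 si groove replicate 3 lies apart for WNT2B, HOXA13 and HOXD13.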

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

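Of the tests in this part, the leave-one-out values of the share of genes going the same way were chosen after the result was seen. The 46 single genes, those printed for the tray comparisons, were also picked with the results of these comparisons in view. The tray effect was tested for a difference between the si arm and the c arm, and 7654 genes differed, 40.9% of those tested. Values here are the log2 change in the si arm minus that in the c arm, and d14 si groove is the only one of the 4 groups from run0208, so run enters each of them. Of 46 genes named in the tray comparisons 34 differed, and 12 did not pass, among them NDRG1, VEGFA, MCM4, PECAM1, CDH5, APOB, MTTP and WNT2B.

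Genes of epithelium and matrix differed in both directions. The tray effect was greater in the si arm for CDH1 (2.27), KRT19 (1.76), LAMC1 (0.76), COL12A1 (4.68), ASPN (4.16), DMBT1 (5.93), LYVE1 (6.398), MRC1 (7.08), LOX (1.17) and MT-CO1 (2.18). The difference was also positive for KRT20 (7.28), S100A9 (8.26) and AURKA (0.76), which fell by 6.85, 7.10 and 1.46 with the tray in the c arm, and for KDR (1.30), which rose by 2.51 there. Single matrix and mesenchyme genes with a negative difference were POSTN (-4.39), PDGFRA (-2.83), BGN (-2.43), VIM (-2.15) and COL5A2 (-1.42). Single genes of glucose use and low oxygen with one were GAPDH (-1.62), ENO2 (-1.93), PGK1 (-1.02), SLC2A1 (-0.77), BNIP3 (-1.77) and CA9 (-3.01). Of 20 hypoxia genes 7 had a negative difference, 2 a positive one and 11 did not differ, and the list was not called (adjusted p = 0.149). Differences were negative for HOXA13 (-4.46), HOXD13 (-6.24), LGR5 (-2.64), CDX2 (-2.35) and PCNA (-0.53). For genes with 3 counts or fewer in a group only the adjusted p is given: SOX10 differed at 0.0182, NPPB at 0.0409, LCN15 at 0.000627 and NKX2-3 at 7.96e-05.

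Camera called 16 lists for this difference with the preset correlation and 0 with an estimated correlation, where 9 had an unadjusted p under 0.05. Mitochondrially encoded genes leaned to the si arm in 13 of 13 cases (adjusted p = 2.42e-24, and adjusted p = 0.0845 with an estimated correlation), as did intestinal epithelium genes in 13 of 20, while 3 leaned to the c arm (adjusted p = 9.78e-08, and adjusted p = 0.126 with an estimated correlation). These 3 were CDX1 (-2.29), CDX2 (-2.35) and HNF4A (-2.05). The 13 epithelium genes hold genes of epithelia in general, such as EPCAM, CDH1 and CLDN7, beside KRT20. The call is therefore not particular to intestinal epithelium. A lean to the si arm also held for 16 of 19 interferon response genes, against 1 (adjusted p = 1e-06, and adjusted p = 0.0606 with an estimated correlation) and 10 of 14 antigen presentation genes, against 2 (adjusted p = 9.08e-05, and adjusted p = 0.134 with an estimated correlation). It held too for 10 of 16 unfolded protein response genes (adjusted p = 0.00472, and adjusted p = 0.144 with an estimated correlation) and 7 of 14 histone genes (adjusted p = 1.95e-05, and adjusted p = 0.0606 with an estimated correlation). General mesenchyme leaned to the c arm in 15 of 20 genes (adjusted p = 3.09e-09, and adjusted p = 0.134 with an estimated correlation), and colon and posterior identity in 16 of 17 (adjusted p = 7.83e-08, and adjusted p = 0.126 with an estimated correlation). So did hedgehog signalling in 10 of 13 (adjusted p = 3.34e-06, and adjusted p = 0.178 with an estimated correlation) and neural and glial genes in 12 of 15 (adjusted p = 1.22e-05, and adjusted p = 0.239 with an estimated correlation). Further lists with that direction were WNT ligands and R-spondins, 10 of 21 genes (adjusted p = 0.000116, and adjusted p = 0.193 with an estimated correlation), and BMP signalling, 15 of 19 against 2 (adjusted p = 0.000117, and adjusted p = 0.193 with an estimated correlation). Glycolysis followed with 11 of 17 against 3 (adjusted p = 0.000894, and adjusted p = 0.221 with an estimated correlation) and WNT targets with 8 of 18 against 2 (adjusted p = 0.0107, and adjusted p = 0.491 with an estimated correlation). The weakest were proximal small intestine, 6 of 15 (adjusted p = 0.0112, and adjusted p = 0.332 with an estimated correlation), and pluripotency, 6 of 12 against 1 (adjusted p = 0.0347, and adjusted p = 0.491 with an estimated correlation). Adjusted over the list alone, 17 interferon, 11 antigen presentation, 9 histone, 17 mesenchyme and 13 neural genes passed in the stated direction and 4 intestinal epithelium genes in the other, and the remaining counts were the same.

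Of 60 drawn splits of the libraries within each arm 2, the real one included, called as many genes as the real one, which called 7654. Splits that mix tray and conventional libraries put the tray effects into the spread between libraries. They therefore call fewer genes whether or not the arms differ, and the share cannot tell whether a difference between arms arose by chance. Nor do the splits speak to chance between cultures or to run. The highest other split called 11055 genes and exchanges all d14 c-groove and d14 HCO libraries, so that it tests the sum of both tray effects, a structure of the samples. The next split, with the si arm kept whole and the c arm mixed, called 5574 genes.

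The genes called between d14 si groove and d14 HIO may owe part of their difference to the sequencing runs, run0208 and run0337, each of which holds only 1 of these groups. The library names also give these runs different sets of sequencing indexes, so any difference in library preparation cannot be told apart from run. If run were the whole cause, genes called there and in d14 c-groove against d14 HCO, within run0337, should go the same way in at most 60% of cases, and in more than 75% if it were not. The value was 71.2%, and 69.2 to 74.0% leaving out 1 library. It lies over the 60% set for run as the whole cause but under the 75% set against it. By these bounds the test does not decide whether run was the whole cause. A contribution of run to single genes stays open, and so does the difference of culture that the labels name. For these groups 1 of 10 splits, the real one, called 10764 genes and the highest other 0, too few splits for a share under 0.05.

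The genes called between d14 c-groove and d14 si groove may likewise owe part of their difference to run0337 and run0208. Of genes called both there and in d14 HCO against d14 HIO, within run0337, 87.3% went the same way, over the bound of 75%, which argues against run as the whole cause. A contribution of run to single genes stays open, and so does the difference between the arms, which the labels do not explain. Here the real split called 10434 genes and the highest other of 10 splits 0.

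The other comparisons had 10 splits each, too few for a share under 0.05. The real splits called 9141 genes for d14 c-groove against d14 HCO, 12010 for d14 HCO against d14 HIO, 9402 for d6 si groove against spheroid, 11032 for d14 si groove against d6 si groove and 11124 for d14 HIO against spheroid. The highest other split called 1 gene for d6 si groove against spheroid and 0 in the other 4.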

How the results depend on the processing

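The leave-one-out values of the overlaps and the list members by setting were chosen after seeing the data, and all other alternatives before. Of 220 values of the gene counts under alternatives, 211 stayed within 1.5 times the count reported. Under limma on log2(TPM + 0.1) 3487 genes were higher in d14 si groove than in d14 HIO. From spheroid to d6 si groove 2479 genes fell under limma on log2(TPM + 1) and 2433 under log2(TPM + 0.1). From spheroid to d14 HIO 8952 and 8997 genes rose and 2379 and 2325 fell under these settings. The median log2 change of all genes there was 0.392 and 0.495, against 0.056 from counts. With log2(TPM + 1) this median was -0.104 in d14 c-groove against d14 si groove, where counts gave -0.076. In the difference between arms it was -0.126, where counts gave -0.015. With sequencing run as a term 3149 genes rose and 2929 fell from d6 to d14 si groove. The term rests on d6 si groove replicate 3 against replicates 1 and 2. It cannot tell run apart from a difference of that single library. With the replicate block 7663 genes differed in tray effect. The libraries share only a replicate number: residual correlations of 45 pairs with the same number from different groups had a median of -0.01, and 12 pairs correlated best within their number. Only 2 exceeded 0.1, both between d6 and d14 si groove, at 0.204 for replicate 1 and 0.256 for replicate 3, with 0.084 for replicate 2; there 5554 genes rose and 5455 fell with the block. An estimated correlation left 4 lists called in d14 c-groove against d14 HCO, 1 in d14 HIO against spheroid, and 0 in the other comparisons, where camera gave 5 to 10 lists an unadjusted p under 0.05. With limma on log2(TPM + 1), 74.4% of genes called in both arms moved the same way with the tray (correlation 0.269). Leaving out 1 library gave 69.2 to 74.0% (0.166 to 0.214) for the tray effects and 86.4 to 89.8% (0.549 to 0.620) for the differences between arms. Of 3861 values of 271 named results 3804 kept their side of the threshold, 39 lost the call, 13 gained it and 5 reversed. WNT2B reversed in d6 si groove against spheroid (-0.113 with the run term, -0.102 to 1.101 leaving out 1 library). From d6 to d14 si groove WNT2B (-0.226) and LGR5 (-0.029) reversed with the run term, and GATA4 without d6 si groove replicate 3 (-0.011 to 0.538 leaving out 1 library). None of these was called with the reported settings, and the cause was not tested. Log2 changes from log2(TPM + 1) were closer to 0 by over 1.5-fold in 129 of 257 called named results, and run as a term moved 16 of 74 by that much. In simulated data at this depth 67, 67 and 66 of 18701 genes were changed by 1.5-, 2- and 4-fold. In the 7 comparisons edgeR recovered 28.4 to 43.3%, 59.7 to 82.1% and 93.9 to 98.5% of them with 4 to 10 false calls. For the difference between arms it recovered 8.96%, 34.3% and 72.7%. On the simulated data for d14 si groove against d14 HIO, DESeq2 made 34 false calls and edgeR 4. The real comparisons called 48.9 to 64.2% of genes, far more than were changed here, so these shares need not hold for them.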

Other observations

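The test on genes of the bladder lining was chosen only after such genes had been seen high in d14 HCO, and used 12 markers whose values had not been looked up. KRT7, a keratin gene of simple and transitional epithelia, averaged 2064 ± 80.5 CPM in d14 HCO and 2827 ± 728 CPM in d14 c-groove, against 9.40 ± 1.03 CPM in d14 HIO. UPK1B and UPK2, which encode uroplakins of the urothelial surface, averaged 629 ± 38.0 and 200.0 ± 9.11 CPM in d14 HCO, against 2.92 ± 0.396 and 0.328 ± 0.202 CPM in d14 HIO. GATA3 and TP63, transcription factor genes of urothelium and other stratified epithelia, averaged 252 ± 22.1 and 107 ± 7.96 CPM there. Of 13 such genes 12 were higher in d14 HCO than in d14 HIO by edgeR, and 11 were higher and 1, KRT20, lower in d14 c-groove than in d14 si groove. The exception in d14 HCO was the keratin gene KRT5, at 1.81 ± 0.730 against 2.79 ± 0.292 CPM in d14 HIO. Its log2 difference of -0.63 ± 0.52 did not pass the edgeR test (adjusted p = 0.301).

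Urothelial cells in the d14 HCO cultures are a candidate source of these transcripts. Of the 12 markers not looked up 10, or 83.3%, were higher in d14 HCO, over the bound of 70% set for this explanation. TRIM29 stood at 111 ± 5.58, GRHL3 at 135.5 ± 6.73 and DHRS2 at 98.7 ± 15.97 CPM, while CRTAC1 was lower and ADIRF was not tested. Of all 18701 genes tested 5678 were higher in d14 HCO, and the intestinal epithelium list had a median log2 change of 2.40. The test therefore cannot tell urothelial cells from other epithelial cells. Cornifying squamous cells could also share part of the pattern: of 12 markers 1, KRT10, or 8.33%, was higher, but 8 were not tested and the list left out 6 squamous genes, among them IVL, SPRR3 and KRT13, all higher in d14 HCO, so this excludes nothing. The si arm also expresses many of these genes at 1 CPM or more, 10 of the 13 and 7 of the 12, and 4 of the 13 stand in lists used above. No sort or gate is named in the labels, and whether such cells are meant to be present was not tested.

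In d6 si groove replicate 3 POU5F1, a pluripotency gene, stood at 63.1 CPM, against 12.5 and 9.66 CPM in replicates 1 and 2. The 20 most abundant genes took 13.1 ± 0.0458% of counts in d14 c-groove and 7.31 ± 0.0908% in d14 HIO. Spheroid replicate 3 had 18303 genes with a count, against 21596 and 22469 in replicates 1 and 2.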
